A study of Drosophila melanogaster with 3 samples.

How the data were processed

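The samples are 3 biological replicates of whole Drosophila melanogaster embryos aged 18 to 24 h that express CG2120 fused to enhanced GFP. Per the labels, chromatin was sonicated to 200 to 800 bp and precipitated with an antibody against GFP. The authors deposited peak lists in the narrowPeak format for builds dm6 and dm3, with a list for each replicate, a list from the pooled replicates and an optimal list thresholded by irreproducible discovery rate (IDR). The replicate and pooled lists are labelled as peaks and background, and whether their highest length of 30000 is a limit set by the caller is not given in the sources used here. Per the text deposited with each sample, all lists were called against the same 1 control. The peak caller, the aligner and their versions are not given in the sources used here. The signal value of each peak, as the authors' caller gave it, is not scaled between lists, so it was used only as a rank within a list and as a value in the optimal list. The authors' lists also give the −log10 q value of each peak, which reaches its highest value in 6897 peaks of the optimal dm6 list and was therefore not used for ranking. The summit is the deposited offset from the peak's start. Read files and the control were not used here, so the depth per sample is unknown, and no interval that needs it is given. In dm6 the optimal list is the same as the 8340 strongest peaks of the pooled list, and in dm3 as the 8204 strongest.

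The dm6 lists were used, with the 7 arms 2L, 2R, 3L, 3R, 4, X and Y, and all dm6 peaks lie on these. The dm3 lists served as an alternative, with the arm lengths taken from the last peak on each arm. Genes, exons and TSSs came from the Ensembl annotation of the release 6 genome, with 13968 protein coding genes and 19630 distinct TSSs, and sequence came from the release 6 assembly. The number of top peaks taken from each replicate was that of the optimal list, 8340. Summits within 100 bp counted as the same peak, and chance overlap came from 100 circular shifts along each arm. Each summit was assigned to the classes promoter (within 500 bp of a protein coding TSS), 5' UTR, coding exon, 3' UTR, intron and intergenic, in that order, and compared with 1000 circular shifts of all summits together, two-sided. The smallest p these shifts can give is 0.002. All classes came from protein coding genes only, so intergenic sequence can hold RNA genes. Ranks of signal in promoter and other peaks were compared by a permutation test with 100000 resamples, two-sided, on the difference of medians.

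A gene counted as bound if an optimal summit lay within 500 bp of any of its TSSs. The 41 gene lists were written from textbook knowledge, as gene symbols or as symbol patterns, which can take in other genes. Of their symbols 11 found no gene in the annotation. Each list was compared with all other protein coding genes by Fisher's exact test, two-sided. RNA genes of 7 types, pseudogenes counted among them, were compared with protein coding genes in the same way, by the 5' end of the gene. Consensus sequences of 30 known motifs were searched on both strands within 50 bp of each summit and in a window centred 500 bp away, on a side drawn at random, and compared by the exact McNemar test, two-sided. All 8-mers present in at least 50 windows were tested in the same way, each counted together with its reverse complement. Peaks per Mb on X and on the arms 2L, 2R, 3L and 3R were compared by permuting 500 kb bins. P-values were adjusted by the method of Benjamini and Hochberg within each family, with a threshold of 0.05. Shares of 0 are given with the upper limit that a count of 3 sets, and intervals are at 95%.

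Values of the optimal list are given with the mean and SD of the 3 replicates' own strongest peaks. Leaving out a replicate means keeping the optimal peaks found in the strongest peaks of the other replicates. This kept 6406 peaks without replicate 1, 6318 without replicate 2 and 6611 without replicate 3. The optimal list itself still came from all 3 replicates. The lists, motifs, tests and alternatives were fixed before the data were examined, except where the text says otherwise. The rule for named genes, fixed at the same time, takes CG2120, the genes of the 20 strongest optimal peaks that lie within 100 bp of a top 1000 peak of every replicate, the 10 protein coding genes with the most summits, and members of each list. For a list that was called, these are the 4 bound members with the highest peak and up to 3 unbound members in alphabetical order, and for the others up to 2 of each, of which the text gives a part. The neighbours of CG2120 come from the description of its locus.

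Alternatives were summits within 50 bp, any overlap and reciprocal overlap of at least 50% for the same peak, the top 1000 and top 5000 peaks, the dm3 lists, promoter windows of 200 and 1000 bp, summits placed at random, the upper part of the optimal list by signal (4170 peaks), peaks found in all 3 replicates, each replicate left out, genes matched on length and number of TSSs, motif windows of 100 bp on each side, TSSs of genes with no peak as the control, promoter peaks and other peaks apart, and bins of 250 and 1000 kb. After the data were seen, windows of the same feature class and GC content were added as a control for motifs and 8-mers, RNA genes more than 1 kb from a protein coding TSS were added for the RNA types, and genes matched on head-to-head arrangement and number of TSSs were added for the gene lists. Values outside the fixed design, added later, are the positions relative to TSSs, the trend along the pooled list, the GC content around summits and, in the closing section, the tests of GC content, paired genes, transposon insertions and peak strength by motif. Paired genes have TSSs on opposite strands that point away from each other within 500 bp. Their binding was also counted with each summit credited only to the gene of its nearest TSS. Intervals of odds ratios are Woolf's and treat genes as independent, and those of GC differences come from 2000 bootstrap samples of peaks. Matched genes were drawn 10000 times, so the smallest p is 0.0002. Control windows at TSSs of genes with no peak lay at the summit's own offset from such a TSS, on the same arm. No comparison between groups, no test for outlying samples and no splits of the samples were run, since there is 1 group of 3.

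The methods were tested on simulated data. On scattered summits 0 features were called, and planted promoter summits were called. Of 20 gene lists of 50 genes with odds planted 4 times higher 20 were called, and of 20 without it 0 were. Genes were drawn as independent, so this does not show how often smaller lists or smaller differences are missed. A planted 8-mer came out at rank 1, a planted motif was called with 0 of 29 others, and planted X ratios of 1.00 and 1.30 were recovered. The simulated windows lay at scattered places and were not made to differ from their flanks in GC content, as real summits do. So the simulation does not show how many motif and 8-mer calls follow base composition. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.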

Results

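Chromatin immunoprecipitation followed by sequencing was done on whole Drosophila melanogaster embryos aged 18 to 24 h, late in embryonic development. The embryos carried a transgene for CG2120 fused to enhanced GFP, and the fusion protein was precipitated with an antibody against GFP. CG2120 (FBgn0030005, dm6, X:8135824 to 8137046) is annotated with 2 exons and 315 codons, and its predicted protein matches the pattern of a C2H2 zinc finger 7 times. The data are 1 group of 3 biological replicates, with a peak list for each replicate, a list from the pooled replicates and an optimal list of reproducible peaks. No second group was measured, so the comparisons are between replicates and between parts of the genome. In build dm6, replicates 1 and 2 and the pooled list hold 30000 peaks each, replicate 3 holds 27353, and the optimal list holds 8340 with a median width of 450 bp. Per the labels, the replicate and pooled lists hold peaks and background as input for the selection of reproducible peaks, and the sources used here do not say whether 30000 was an upper limit. The lists give no read counts, so the depth of each sample is unknown, and intervals on shares of peaks or genes cover counting error only. The question is where in the genome this zinc finger protein is found at the end of embryonic development.

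The replicates gave largely the same sites. Among their 8340 strongest peaks, replicates 1 and 2 shared 80.4%, replicates 1 and 3 shared 77.6% and replicates 2 and 3 shared 78.0%, counting summits within 100 bp of each other as the same. The mean of the 3 pairs was 78.7% ± 1.53 (SD, n = 3), against a mean of 1.25% to 1.27% and a highest value of 1.55% for lists shifted along each chromosome arm. Signal values of optimal peaks found in both replicates had a Spearman correlation of 0.878 for replicates 1 and 2 across 7921 peaks, 0.862 for replicates 1 and 3 across 7820 and 0.862 for replicates 2 and 3 across 7800. These correlations are across peaks, which are not independent replicates. Of the optimal peaks, 86.9% ± 2.72 (SD, n = 3) were among the strongest 8340 of a replicate, and 5869 (70.4%, exact 95% interval 69.4 to 71.4) were among those of all 3. That share was 97.8% in the fifth of the optimal list with the highest signal and 10.8% in the fifth with the lowest, and 73 optimal peaks were in none of the 3. The replicates were cut at the rank that ends the optimal list, so its weakest peaks can miss the cut by a small change of rank. Anywhere in the full lists, which include background, replicates 1, 2 and 3 held 97.4%, 97.3% and 95.9% of the optimal peaks. The optimal list is the top of the pooled list by signal, so it was made from the same replicates it is compared with here.

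CG2120-GFP was enriched at promoters of protein coding genes and hardly ever found in coding sequence outside them. Of the 8340 optimal summits, 4120 (49.4%) lay within 500 bp of a transcription start site (TSS), 4.32 times the 11.4% of shifted summits, and 4220 lay elsewhere. With a promoter window of 200 bp the share was 37.5% and with 1000 bp 58.6%. The share was 49.3% ± 0.882 (SD, n = 3) in the strongest peaks of the replicates. Outside promoters, coding exons held 16 summits, 0.192% against 13.9% of shifted summits, and 3' untranslated regions (UTRs) held 0.947% against 4.55%. Promoter summits that lie in coding sequence were not counted apart. Sequence outside protein coding genes and promoters, here called intergenic, held 13.9% against 29.95%, and introns held 35.0% against 39.3%. The adjusted permutation p of these 5 classes was 0.0024, from the smallest p that 1000 shifts can give, 0.002 (two-sided). In 5' UTRs outside promoters the share was 0.576% against 0.795%, with an adjusted permutation p of 0.038. That last difference was not called in peaks found in all 3 replicates (0.562%, p = 0.0559 by permutation), without replicate 1 (0.562%, p = 0.0539 by permutation) or without replicate 3 (0.62%, p = 0.152 by permutation). Shifted summits can fall anywhere on an arm, and 5.80% of them fell in annotated transposon insertions, against 0.240% of real summits. Whether poor placement of reads in repeats widens the differences from shifted summits was not tested.

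**Figure D1:**
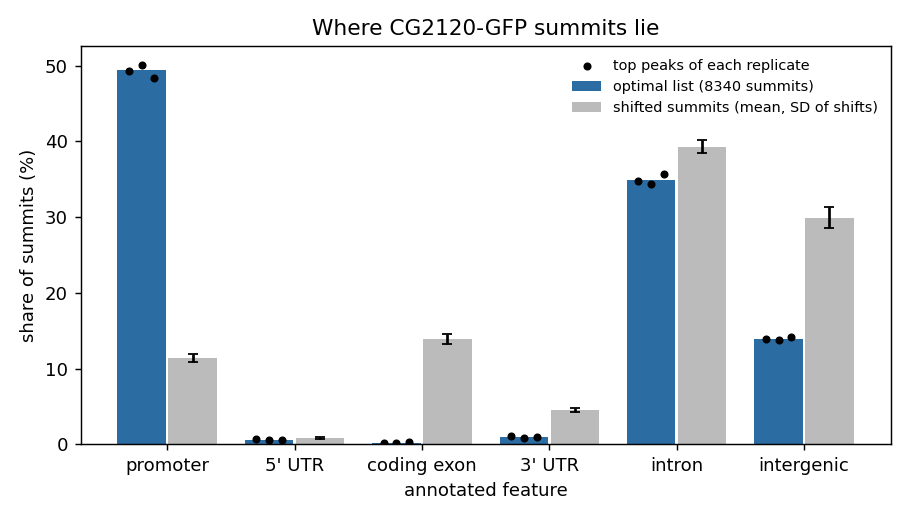
Share of CG2120-GFP summits in each annotated feature, in percent: blue bars are the optimal list, grey bars the mean of 1000 shifted copies with their SD, and black points the strongest peaks of each of the 3 replicates. Promoters hold 49.4% of summits against 11.4% in shifted copies, and coding exons outside promoters hold 0.192% against 13.9%.

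Promoter summits lay just upstream of the start site, at a median of -84 bp (quartiles -170 and -24), and 82.1% were upstream of the nearest TSS. In the replicates 81.5% ± 0.631 (SD, n = 3) were upstream. Another 2586 summits (31.0%) lay more than 2000 bp from any protein coding TSS. Promoter peaks were also the stronger ones. Their median rank by signal was at percentile 57.4 of the optimal list, and that of the other peaks at 43.4, a difference of 14.0 points (permutation p = 1e-05, the smallest that 100000 resamples can give). The difference was 14.3 ± 1.53 points (SD, n = 3) in the replicates. Down the pooled list, which includes background by design and whose lowest −log10 q is 0.164, the promoter share went from 54.6% in the 5000 strongest peaks to 17.1% in ranks 25001 to 30000, and the coding exon share went from 0.14% to 8.38%.

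**Figure D2:**
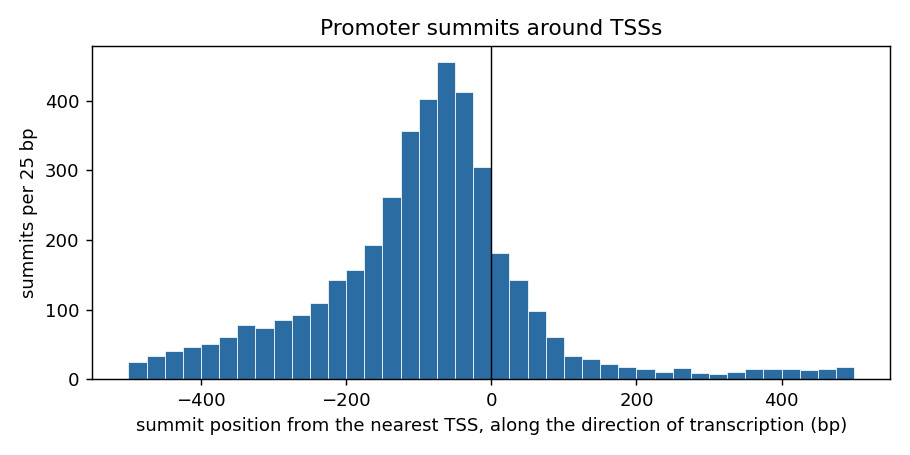
Number of promoter summits of the optimal list by position relative to the nearest protein coding TSS, in bp, with negative values upstream. The summits pile up just upstream of the start site, with a median of -84 bp.

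**Figure D3:**
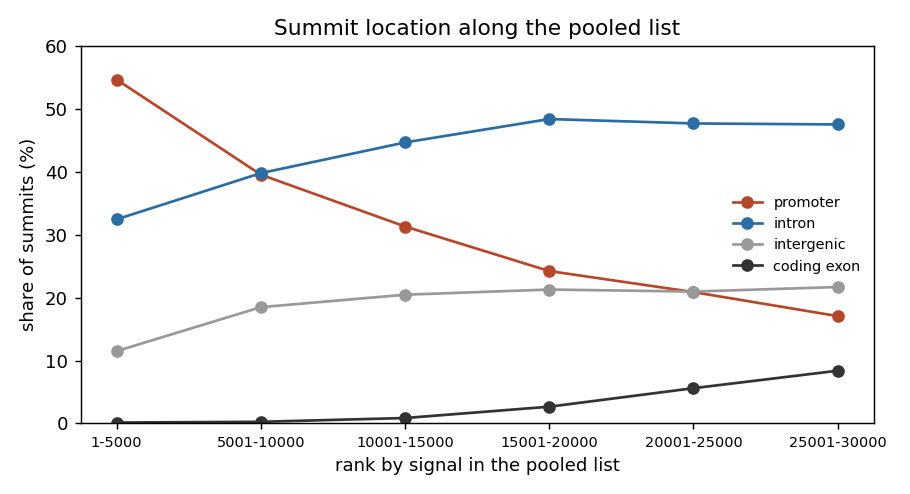
Share of pooled peaks in promoters, introns, intergenic sequence and coding exons, in percent, in groups of 5000 peaks by signal rank; the list includes background. Promoters fall from 54.6% to 17.1%, and coding exons outside promoters rise from 0.14% to 8.38%.

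The strongest peak of the optimal list and of all 3 replicates lay at 2L:480556 to 481415 in build dm6, in an intron of ush, which encodes a cofactor of GATA factors, and 1393 bp upstream of the TSS of cbt, which encodes a zinc finger transcription factor. Its signal value was 9422, and the 31 bases centred on its summit read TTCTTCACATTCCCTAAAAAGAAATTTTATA. The next peaks were at the promoter of CG14100 (signal 7987, 3L:19590293 to 19590908), in an intron of CG11050, 1026 bp from its TSS (signal 7218, 2L:6612395 to 6612984), and at the promoter of Ugalt, which encodes a UDP-galactose transporter (signal 7175, X:2703599 to 2704159). Of the 20 strongest reproducible peaks, 14 were at promoters, 5 in introns and 1 in intergenic sequence. Besides CG14100 and Ugalt, the promoters were those of CG8320 (signal 5460), the mitochondrial ribosomal protein gene mRpL41 (5385), Tcs5 (5020), PNPase (4755), Art3 (4712), CenG1A (4570), the chromatin protein gene Chro (4519), the signalling adaptor gene Shc (4409), the translation factor gene eIF6 inside ytr (4326), larp (4278), Pal1 (4190) and CG1888 (4176). The other intronic peaks lay in the kinase gene Lk6 (signal 4981, 969 bp from the TSS), in CG9663 (4313) and in CG32772 (4117). The intergenic peak lay 5055 bp from CG4004 on X at 12750774 to 12751741, with a signal of 5019. Of the 1000 strongest optimal peaks, 844 lay within 100 bp of a peak among the 1000 strongest of every replicate.

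The gene with the most summits, counting 2 kb around it, was kirre (FBgn0028369, X:2740384 to 3134532), an immunoglobulin family gene of myoblast fusion, with 33 over 394149 bp. Next came shn (FBgn0003396, 2R:11159086 to 11217394), a zinc finger transcription factor gene of BMP signalling, with 22 over 58309 bp, and the kinase gene Tlk (FBgn0283657, X:3720007 to 3789770) and ush (FBgn0003963, 2L:476220 to 540560) with 20 each. The transcription factor gene sbb (2R) held 19 and CG1677 (X) held 18. CG32264 (3L), SNF4Agamma (3R), a subunit gene of AMP-activated kinase, and tara (3R) held 16 each, and the forkhead family gene CHES-1-like (X) held 15. Longer genes can hold more summits, and these counts were not tested.

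Of 13968 protein coding genes, 4747 (34.0%) had a summit within 500 bp of a TSS, and the share was 33.7% ± 0.645 (SD, n = 3) in the replicates. Promoters of several groups of genes for basic cell functions were bound more often than those of other genes. Cytoplasmic ribosomal protein genes had a promoter summit in 68 of 86 cases (79.1%, against 33.7% of all other genes), among them RpL34b (signal 1547), RpS20 (1305), RpL7 (1166) and RpS27 (1089), but not RpL10Aa, RpL15 or RpL21. Proteasome subunit genes were bound in 24 of 32 cases (75%), among them Rpn5 (1104), Rpn3 (826), Rpn6 (737) and Rpt5 (544), but not Prosalpha1, Prosalpha3 or Prosbeta2. Genes of glycolysis were bound in 11 of 13 cases (84.6%), led by Gapdh2 (2899), Eno (1718), Hex-A (1330) and Ldh (878), with Gapdh1 and Pfk unbound. Aminoacyl-tRNA synthetase genes were bound in 13 of 17 cases (76.5%), led by SerRS (1721), IleRS (807), ThrRS (767) and AsnRS (523). Translation initiation and elongation factor genes were bound in 29 of 52 cases (55.8%), led by eIF6, eIF4EHP (1466), eIF3h (1136) and eIF3c (1095), and respiratory chain genes in 39 of 84 (46.4%), led by ND-ASHI (1654), ND-MWFE (1355), ND-24 (912) and COX5A (805). Autophagy genes were bound in 14 of 20 cases (70.0%), with Atg17 (1273), Atg2 (1076), Atg18a (918) and Atg7 (754) the strongest and Atg1, Atg10 and Atg101 unbound.

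Genes of chromatin regulation and cell division were also bound often. Polycomb and Trithorax group genes were bound in 20 of 26 cases (76.9%), led by ph-p (signal 3994), brm (1420), Sfmbt (816) and Su(z)12 (720), but not ash1, osa or Pcl in the optimal list, though osa was bound in the strongest peaks of 1 replicate. Cell cycle genes were bound in 20 of 30 cases (66.7%), led by Dp (1387), aurA (742), dup (727) and Mcm2 (577), with CycB, CycB3 and CycE unbound in the optimal list, but CycB bound in the strongest peaks of 2 replicates and CycB3 and CycE in those of 1. Genes of insulator and architectural proteins were bound in 12 of 19 cases (63.2%), led by Chro, Cp190 (1420), Trl (1300) and pzg (572), with dwg, Elba1 and Elba2 unbound. Hippo pathway genes were bound in 9 of 14 cases (64.3%), led by hpo (985), Mer (708), yki (566) and kibra (519), with CycE, Diap1 and ds unbound in the optimal list.

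By Fisher's exact test (two-sided, adjusted over 41 lists), these 11 lists were bound more often than other genes. In the replicates (mean ± SD, n = 3) the share was 77.9% ± 6.15 for ribosomal proteins and 71.9% ± 3.125 for the proteasome. Glycolysis stood at 74.4% ± 8.88, aminoacyl-tRNA synthetases at 66.7% ± 6.79 and translation factors at 50% ± 6.93. The respiratory chain had 43.7% ± 4.18, autophagy 68.3% ± 2.89 and Polycomb and Trithorax 76.9% ± 3.85. Cell cycle genes had 66.7% ± 0, insulator proteins 56.1% ± 6.08 and Hippo 64.3% ± 7.14. Adjusted p was 1.44e-16 for ribosomal proteins, 2.83e-05 for the proteasome, 5.39e-05 for Polycomb and Trithorax, 0.00105 for glycolysis, 0.00119 for cell cycle and 0.00144 for aminoacyl-tRNA synthetases. It was 0.0042 for autophagy, 0.0051 for translation factors, 0.0309 for insulator proteins, 0.0462 for the respiratory chain and 0.0493 for the Hippo pathway. The calls for ribosomal proteins, proteasome, Polycomb and Trithorax and autophagy held under the 8 alternative settings fixed in advance. By the same exact test, the call for the respiratory chain was lost without replicate 1 (adjusted p = 0.722), without replicate 2 (0.781) and without replicate 3 (0.378), and that for insulator proteins likewise (0.0925, 0.0856 and 0.0884). The Hippo call was lost without replicate 1 (0.0914) and without replicate 2 (0.0832), that for translation factors without replicate 1 (0.176) and without replicate 2 (0.134), and that for aminoacyl-tRNA synthetases without replicate 1 (0.127). These settings keep fewer peaks of the same optimal list, so a lost call need not come from the replicate left out. With a replicate left out, the difference from other genes was 28.3 to 34.7 percentage points for Hippo (30.3 in the full list) and 23.1 to 24.1 for insulator proteins (29.2). It was 24.1 to 30.3 for aminoacyl-tRNA synthetases (42.5), 11.6 to 16.6 for translation factors (21.9) and 2.39 to 6.16 for the respiratory chain (12.5). In the 4170 strongest peaks the exact test did not call translation factors (0.123), the respiratory chain (0.63), Hippo (0.317), insulator proteins (0.114) or the cell cycle (0.0672). In peaks of all 3 replicates it did not call translation factors (0.158), aminoacyl-tRNA synthetases (0.0724), the respiratory chain (0.752), Hippo (0.075) or insulator proteins (0.146). Glycolysis (0.0981) and Hippo (0.32) were not called with a 200 bp window, nor the respiratory chain with 1000 bp (0.0617). Against genes matched on length and number of TSSs, glycolysis (84.6% against 53.4%, adjusted permutation p = 0.0734), Hippo (64.3% against 41.7%, 0.203) and insulator proteins (63.2% against 39.5%, 0.0842) were not called. Against genes matched on head-to-head arrangement and number of TSSs, chosen after seeing the data, autophagy was not called (70.0% against 46.6%, adjusted permutation p = 0.0959), nor were aminoacyl-tRNA synthetases (76.5% against 54.7%, 0.16), glycolysis (84.6% against 56.4%, 0.103), the respiratory chain (46.4% against 43.4%, 0.821), Hippo (64.3% against 40.1%, 0.16) or insulator proteins (63.2% against 40.2%, 0.103).

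**Figure D4:**
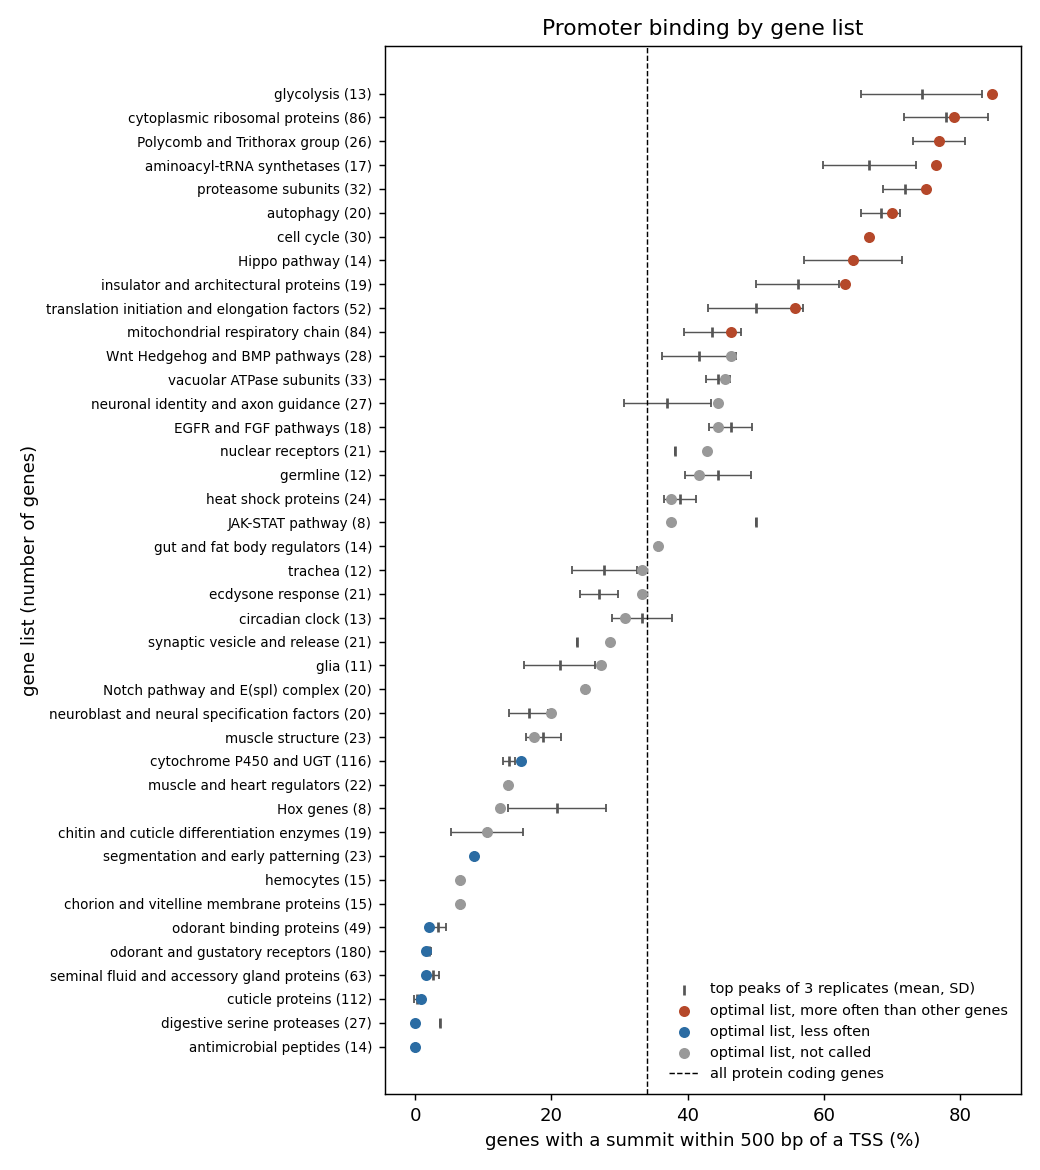
Share of genes with a summit within 500 bp of a TSS, in percent, for each of the 41 gene lists with its number of genes; circles are the optimal list, coloured by the call, and grey bars the mean and SD of the strongest peaks of the 3 replicates. Glycolysis (84.6%) and ribosomal proteins (79.1%) stand at the top, and digestive proteases and antimicrobial peptides (0 genes bound in the optimal list) at the bottom.

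The 8 lists bound less often than other genes hold gene families of the cuticle, the chemical senses, male reproduction, digestion, detoxification and defence, and genes of early patterning. Cuticle protein genes, which build the exoskeleton, were bound in 1 of 112 cases (0.893%), Lcp9, which only 1 replicate held among its strongest peaks, and not at Acp65Aa, Ccp84Aa or Ccp84Ab. Odorant and gustatory receptor genes were bound in 3 of 180 cases (1.67%), Ir60e, Gr63a and Gr21a, odorant binding protein genes in 1 of 49 (2.04%), Obp83g, and seminal fluid and accessory gland protein genes in 1 of 63 (1.59%), Sfp26Ad. None of 27 digestive serine protease genes was bound in the optimal list, alphaTry, betaTry and deltaTry included, which allows a share of up to 11.1%. Their share was 3.70% ± 0 (SD, n = 3) in the strongest peaks of the replicates. None of 14 antimicrobial peptide genes was bound, AttA, AttB and AttC included, which allows up to 21.4%. Cytochrome P450 and UGT genes were bound in 18 of 116 cases (15.5%), led by Cyp6u1 (signal 1752), Cyp6a2 (521), Cyp317a1 (514) and Ugt316A1 (426). Segmentation and early patterning genes were bound in 2 of 23 cases (8.70%), bcd (333) and ptc (242), and not at cad, en or eve. Adjusted p by Fisher's exact test was 1.41e-26 for receptors, 8.25e-18 for cuticle proteins, 1.89e-09 for seminal fluid proteins, 4.50e-07 for odorant binding proteins, 5.77e-05 for P450 and UGT, 7.89e-05 for digestive proteases, 0.0104 for antimicrobial peptides and 0.02 for segmentation. By the same exact test, the segmentation call was lost without replicate 1 (adjusted p = 0.0925), without replicate 2 (0.0856) and without replicate 3 (0.0829), in the 4170 strongest peaks (0.317) and in peaks of all 3 replicates (0.132). Its difference from other genes was -25.3 points in the full list and -20.9 to -19.9 with a replicate left out. The call for antimicrobial peptides was lost with a 200 bp window (0.0603), in the 4170 strongest peaks (0.114) and against genes matched on length and number of TSSs (permutation, 0.356). Against genes matched on head-to-head arrangement and number of TSSs, chosen after seeing the data, the calls for P450 and UGT (15.5% against 23.0%, adjusted permutation p = 0.103), segmentation (8.70% against 22.0%, 0.306) and antimicrobial peptides (0% against 19.5%, 0.16) were lost.

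The other 22 lists, most of them developmental regulators and differentiated tissues, were not called. Among neuronal identity and axon guidance genes 44.4% were bound, led by the neuronal RNA-binding protein gene elav (signal 2273) and PlexA (470), with Appl and brp unbound. Shares were 28.6% for synaptic genes, 20% for neuroblast factors, 27.3% for glia, led by moody (2543), 33.3% for trachea, 35.7% for gut and fat body regulators, led by bowl (1422), and 41.7% for germline genes. Muscle structure genes were bound in 17.4% of cases, led by the titin-like gene sls (1000.6), muscle and heart regulators in 13.6%, tin (425) and Mef2 (231) included, and hemocyte genes in 6.67%. Enzymes of chitin and cuticle differentiation were bound in 10.5%, mmy and t, each in the strongest peaks of 2 replicates, and Hox genes in 12.5%, Dfd alone. Signalling lists had shares of 46.4% for Wnt, Hedgehog and BMP, led by nkd (734), 44.4% for EGFR and FGF, led by spi (1716), 37.5% for JAK-STAT, 25% for Notch and the E(spl) complex, and 33.3% for the ecdysone response, led by Eip75B (1003). Vacuolar ATPase genes stood at 45.5%, heat shock proteins at 37.5%, led by Hsp27 (1426), the circadian clock at 30.8%, led by sgg (1743), and nuclear receptors at 42.9%, led by Hr96 (1429). The list of chorion and vitelline membrane proteins (6.67%) was built by symbol and took in Cp190 and Cp110, which are no eggshell proteins, and Cp190 was its only bound member. The lowest adjusted p among these 22 lists by Fisher's exact test was 0.0527, for hemocytes and for the chorion list. The chitin list (0.0554) was called lower without replicate 1 (0.00613), without replicate 2 (0.0117), with a 200 bp window (0.019), in peaks of all 3 replicates (0.0119) and against genes matched on length and number of TSSs (permutation, 0.0169). Against the same matched genes the muscle structure (permutation, 0.00273), muscle regulator (0.0158) and hemocyte (0.00902) lists were also called lower, as were synaptic genes in the 4170 strongest peaks (0.0243) and the chorion list with a 1000 bp window (0.0296).

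RNA genes, here with pseudogenes counted among them, were bound less often than protein coding genes. Of the protein coding genes 31.5% had a summit within 500 bp of the 5' end of the gene. Transfer RNA genes were bound in 33 of 290 cases (11.4%), snoRNA genes in 21 of 269 (7.81%), miRNA genes in 58 of 741 (7.83%), ncRNA genes in 260 of 2548 (10.2%) and pseudogenes in 12 of 330 (3.64%). None of 99 rRNA genes was bound, which allows a share of up to 3.03% if the genes count as independent. How well reads can be placed in repeated copies of RNA genes was not tested. Each annotated entry counted as a separate gene, and whether several entries share a locus was not examined. The 32 snRNA genes were bound in 7 cases (21.9%) and did not pass the test (adjusted p = 0.34, Fisher's exact test). Adjusted p for the other 6 types was between 5.63e-125 for ncRNA and 1.94e-15 for tRNA. With a 1000 bp window the snoRNA difference from protein coding genes shrank from -23.7 to -6.79 percentage points (adjusted p = 0.0246, Fisher's exact test). Among RNA genes more than 1 kb from a protein coding TSS, an alternative chosen after seeing the data, 17 of 211 tRNA genes (8.06%), 102 of 1785 ncRNA genes (5.71%) and 0 of 248 pseudogenes, which allows a share of up to 1.21%, were bound.

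Several core promoter motifs and insulator sites were more frequent at summits than beside them, but the initiator was not. The DNA replication related element (DRE), the TATCGATA site of the factor Dref, lay within 50 bp of 2.95% of summits against 0.252% of windows 500 bp away, in 5.61% of promoter peaks and 0.355% of other peaks. Ohler motif 7 was at 4.89% against 1.62%, Ohler motif 1, the site of M1BP, at 0.671% against 0.0959%, Ohler motif 6 at 0.54% against 0.0719%, and the site pair of the insulator protein BEAF-32 at 0.252% against 0.036%. The CTCF core was at 1.15% of summits against 0.264%, with 0.947% in promoter peaks and 1.35% in other peaks, and the Su(Hw) core at 0.264% against 0.048%. A-rich and T-rich motifs were also more frequent at summits: the TATA box (6.99% against 3.49%), the homeodomain site (8.61% against 5.80%), the forkhead site (7.87% against 4.87%), the GATA site (8.92% against 7.41%) and the Mef2 site (0.516% against 0.276%). Lower at summits were the GAGA site of Trl (1.22% against 2.41%), the E-boxes CAGCTG (4.14% against 5.59%), CACGTG (0.827% against 1.58%) and CACCTG (2.72% against 4.00%), and the sites of Sox (2.13% against 3.20%), Runt (1.93% against 2.60%) and nuclear receptors (0.0959% against 0.264%). The initiator was at 8.61% against 9.41% and was not called. In promoter peaks it was lower than at the same offset from TSSs of genes with no peak (8.20% against 14.3%, adjusted p = 1.03e-17, exact McNemar test).

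By the exact McNemar test (two-sided, adjusted over 30 motifs), 12 motifs were called higher and 7 lower at summits. Adjusted p was 2.18e-48 for DRE, 7.22e-33 for Ohler motif 7, 2.25e-14 for forkhead and 1.18e-11 for CTCF. The other 11 motifs, those of Zelda, the initiator, Pho, Grainyhead, AP-1, CREB, POU, Ets, STAT, ewg and Tinman, were not called, and the lowest of their adjusted p was 0.0744, for STAT. CTCF and forkhead were called under all 10 alternative settings, and Mef2 under none of them, with an adjusted p of 0.37 without replicate 1, 0.143 without replicate 2 and 0.0974 without replicate 3. Outside promoters, by the exact test, DRE (adjusted p = 0.331), Ohler motifs 1 (1), 6 (0.838) and 7 (0.662) and BEAF-32 (1, in 1 summit window and 1 control window) were not called, and against TSSs of genes with no peak, where 7 of the 19 calls were kept, Ohler motifs 1 (0.126) and 6 (0.129) and Su(Hw) (0.107) were not. Against windows of the same feature class and GC content, a control chosen after seeing the data, 10 of the 19 calls were kept. The TATA box (-0.839 percentage points) and the homeodomain site (-1.01) turned to lower without a call, and GATA (adjusted p = 0.879, exact McNemar test) and Su(Hw) (0.0902) were not called. The GAGA site (0.192 points), CACGTG (0.0719) and CACCTG (0.264) turned from lower to higher without a call, and the E-box CAGCTG turned to higher with a call (1.08 points, adjusted p = 0.000848, exact McNemar test). Calls by the exact test were lost without replicate 2 for BEAF-32 (adjusted p = 0.0515) and the nuclear receptor site (0.0787). Over the 10 settings the nuclear receptor call was lost in 5, those for Runt and Su(Hw) in 4, BEAF-32 in 3 and Sox in 2. The call for the E-box CAGCTG was kept in 6 of the 10 and that for CACGTG in 7. Those for CACCTG, TATA, GATA and Ohler motifs 1 and 6 were kept in 8. Motifs not called against flanking windows gained calls by the exact test under some settings. STAT was higher without replicate 1 (0.0417), without replicate 2 (0.0446), with 100 bp on each side (0.0375) and outside promoters (1.33 points, 0.00137), and Grainyhead was higher without replicate 1 (0.00216). POU was lower with 100 bp on each side (-0.851 points, 0.00185) and against GC-matched windows (-0.635 points, 0.00408). Pho was lower in the 4170 strongest peaks (0.0464) and against GC-matched windows (0.0342), and Zelda with 100 bp on each side (0.0215) and against TSSs of genes with no peak (0.0457).

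Among all 9359 8-mers tested, 2204 were more frequent at summits and 1003 less frequent. TATCGATA led the list, followed by ATCGATAG (2.91% against 0.3%), and CAACACTG was at 2.05% against 0.264%. A-rich and T-rich 8-mers such as ATTTTAAA (4.95% against 1.53%) and TTTAAAAA (5.72% against 2.05%) were higher, and CACACACA was lower (1.09% against 4.44%). Against windows of the same feature class and GC content, 227 of 8834 8-mers were higher and 57 lower, and 191 of the 227 were also higher against flanking windows. TATCGATA (2.95% against 0.492%), ATCGATAG, CAACACTG (0.312% in matched windows) and ATCGATAA led that list too. CAGCCCTG was at 1.15% of summits against 0.0959% of matched windows.

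Summits lay in AT-rich DNA. The 101 bp around a summit had a mean GC content of 35.3% (SD 8.94 across 8340 peaks), against 43.8% in windows 500 bp away, and 72.7% of peaks were lower than their own flank. In the replicates the summit value was 35.6% ± 0.415 and the flank value 43.8% ± 0.124 (SD, n = 3). Peaks in the fifth with the highest signal had 32.9% and those in the fifth with the lowest 36.4%, promoter peaks 36.9% and other peaks 33.8%.

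**Figure D5:**
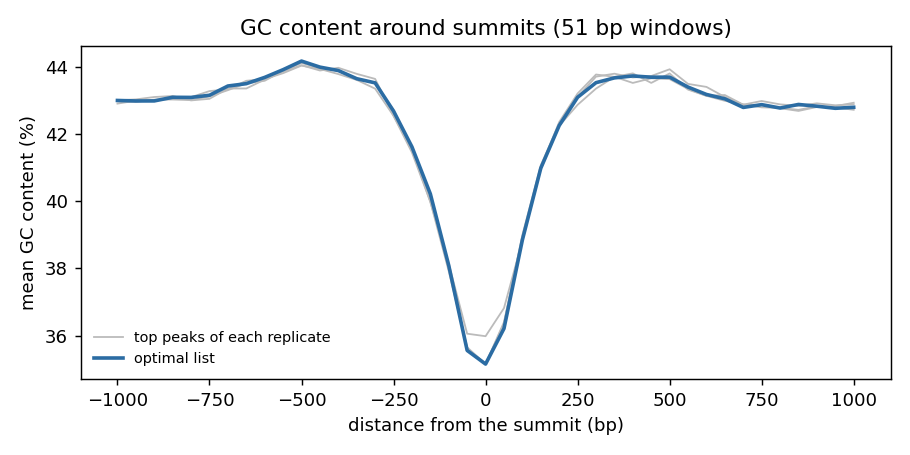
Mean GC content, in percent, of 51 bp windows by distance from the summit in bp; the blue line is the optimal list and the grey lines are the strongest peaks of each replicate. The lines drop at the summit, where the 101 bp mean is 35.3%, and rise on both sides.

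Peaks were spread over all arms except Y. The X chromosome held 70.0 peaks per Mb and the large autosomal arms 61.3, a ratio of 1.14 (permutation p = 0.111 over 47 and 217 bins of 500 kb, two-sided), which did not pass the test. The ratio was 1.12 ± 0.021 (SD, n = 3) in the replicates. Chromosome 4 held 38 peaks, 28.2 per Mb, and Y held 0 of the 8340.

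No optimal summit lay inside CG2120 itself. Within 20 kb of the gene there were 8 summits, 194 per Mb, against 70.0 per Mb over X. The nearest, at X:8135091, was 733 bp from the TSS of CG2120, at rank 5335 with a signal of 189.7, and lay closer to cyr. The strongest, at X:8143748, had a signal of 1717 and rank 145, and lay 87 bp from the TSS of CG17982. It was at rank 154, 139 and 144 in replicates 1, 2 and 3. The others lay near Smox, alpha-PheRS, CG10958, Gclc and CG18262. The density around CG2120 was not tested, nor whether DNA carried with the transgene adds to the signal there.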

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

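The single result here comes from scaffolds of build dm3 outside the major arms, and no test was chosen after it was seen. Whether these sites lie on the arms of dm6, the build of the comparisons above, was not examined. In the dm3 lists, 4 optimal peaks lie on scaffolds outside the major arms, which hold heterochromatin. On 3LHet there are peaks at 1394973 to 1395422 (signal 225.1, rank 4396) and at 1395191 to 1395640 (signal 144.1, rank 7049). On XHet there are peaks at 70612 to 71061 (signal 164.4, rank 6131) and at 76096 to 76545 (signal 128.3, rank 7925). Each overlaps a peak in the lists of all 3 replicates, which also hold background. No control values for these places were analysed here, and no biological explanation was tested, since there is 1 group only.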

How the results depend on the processing

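Tests chosen after seeing the data were those with GC-matched windows for motifs and 8-mers, with RNA genes over 1 kb from a protein coding TSS and with genes matched on head-to-head arrangement and number of TSSs. Counting each result under each alternative, the main results of the comparisons kept their direction and call or stayed within their spread 59 times and moved 21 times. A number of calls was taken as kept up to a ratio of 1.5 to the main number, whichever lists or motifs were called, so single calls changed among these too. Under the settings taken as kept, 13 to 19 gene lists were called, with 12 to 18 of the main 19 among them, and 13 to 20 motifs, with 10 of the main 19 among the 13 against GC-matched windows. Results for single lists, motifs, RNA types and features stayed the same 588 times, lost their call 86 times, gained one 22 times and reversed 54 times. The cause was not tested except where stated. Shared peaks between replicates moved from 78.7% to 66.2% with summits within 50 bp, 85.9% with any overlap, 73.3% with reciprocal overlap, 89.8% in the top 1000 and 83.4% in the top 5000, and ranged from 77.6% to 80.4% with a replicate left out. Peaks found in all replicates moved from 70.4% to 56.1% with summits within 50 bp, 79.0% with any overlap and 58.5% with reciprocal overlap, and ranged from 75.8% to 79.3% with a replicate left out, where fewer replicates have to hold the peak. Called gene lists moved from 19 to 10 against genes matched on head-to-head arrangement, and motif calls from 19 to 9 with TSSs of genes with no peak as the control and to 11 outside promoters. Called 8-mers moved from 3207 to 8157 with 100 bp on each side, where more 8-mers reach the minimum number of windows, to 316 with TSSs of genes with no peak, 1138 in promoter peaks, 1129 outside promoters, 1283 in the 4170 strongest peaks, all of these with fewer 8-mers tested, and to 284 with GC-matched windows. Reversed gene lists were never called on either side, with these differences from other genes in percentage points. Gut and fat body regulators were at -19.0 with a 200 bp window, -2.38 with 1000 bp, -13.2 against matched genes and -0.295 to 6.13 with a replicate left out. With 1000 bp glia were at 7.37 and the ecdysone response at 4.77. In the 4170 strongest peaks neuronal genes were at -10.8, Notch at 3.16, Wnt, Hedgehog and BMP at -3.99, JAK-STAT at -9.35 and the circadian clock at 8.94. In peaks of all 3 replicates neuronal genes were at -1.37 and the clock at 3.48, and with a replicate left out at -2.95 to 3.75 and 1.18 to 2.20. Against matched genes heat shock proteins were at -0.621, neuronal genes at -2.86, Notch at 0.262, JAK-STAT at -5.11 and nuclear receptors at -6.95. Against genes matched on head-to-head arrangement trachea were at 4.39, gut and fat body regulators at -3.35, Notch at 1.53 and JAK-STAT at -2.15. Reversed motifs, in percentage points, were not called under that setting apart from the E-box CAGCTG with GC-matched windows (1.08). Grainyhead was at -0.108 with 100 bp on each side. With TSSs of genes with no peak CACGTG and CREB were at 0.0485 each, TATA at -0.437, GATA at -1.04, Ets at 0.243 and Tinman at -0.218. In promoter peaks CAGCTG was at 0.0971 and Tinman at -0.17, and outside promoters Zelda at 0.237 and AP-1 at -0.0474. With a replicate left out AP-1 ranged from -0.0624 to 0.0908, Ets from -0.127 to 0.0156, Tinman from -0.125 to 0.0908, Pho from -0.25 to 0.0317 and POU from -0.218 to 0.0791. With GC-matched windows GAGA was at 0.192, Zelda at 0.144, CACGTG at 0.0719, CACCTG at 0.264, TATA at -0.839, the homeodomain at -1.01, CREB at 0.036, Ets at 0.048 and STAT at -0.42. Depth is unknown, so what it limits cannot be stated.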

Other observations

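Tests chosen only after the result was seen were those of the AT-rich summits, of transposon insertions and of transcription itself, and the hypotheses on paired promoters and peak strength were formed after the main results but written before their tests were run, apart from the count by nearest TSS, chosen after the first odds ratio was seen. Genes that start back to back were bound more often than others. Of 3815 protein coding genes with a TSS of the opposite strand upstream within 500 bp, 63.8% had a promoter summit, against 22.8% of the other 10153. The odds ratio was 5.96 (95% interval 5.50 to 6.47). With each summit credited only to the gene of its nearest TSS, the shares were 36.9% and 21.5% and the odds ratio 2.14 (95% interval 1.97 to 2.32). In the replicates the shares were 63.1% ± 0.842 and 22.6% ± 0.572 (SD, n = 3). Such pairs make up 76.5% of aminoacyl-tRNA synthetase genes, 65.6% of proteasome genes and 60% of autophagy genes, but only 39.5% of ribosomal protein genes and 38.5% of translation factor genes, as against 39.4% of vacuolar ATPase genes, a list that was not called. The share was 27.3% of all genes and 1.79% of cuticle protein genes.

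Annotated transposon insertions held 20 summits, 0.240% of all, against 5.80% of shifted summits (permutation p = 0.002, the smallest that 1000 shifts can give). How well reads can be placed in these repeats was not tested.

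The odds ratio of 5.96 states that paired genes are bound more often and explains nothing by itself. Credit of a summit to both genes of a pair can account for much of it, since the odds ratio dropped to 2.14 by nearest TSS, but not for all of it, since that interval stayed above 1. The comparison with 200 shifted copies, whose highest odds ratio lay 4.73 below the observed one, decides nothing, because shifted summits have no preference for promoters that paired starts could share. A larger number of TSSs per gene is not needed, since the odds ratio among genes with 1 TSS was 7.16 (95% interval 6.49 to 7.90), and 2.24 (95% interval 2.02 to 2.49) by nearest TSS. What draws the protein to these promoters stays open, no biological explanation was tested, since there is 1 group only, and openness of the chromatin was not measured.

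Frequent binding at housekeeping promoters is the next pattern, taken as the 6 lists called higher among those of basic metabolism and of protein synthesis and breakdown: ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, proteasome, respiratory chain and glycolysis, without the vacuolar ATPase and heat shock lists, which were not called. Gene length and number of TSSs do not account for it as a whole, since 5 of the 6 lists stayed called against genes matched on both, and glycolysis, with 13 genes, lost its call at a difference of 31.3 percentage points (84.6% against 53.4%), down from 50.7 against other genes. Head-to-head arrangement cannot be told apart: against genes matched on it and on number of TSSs 3 of the 6 stayed called, ribosomal proteins (79.1% against 44.5%), the proteasome (75% against 49.2%) and translation factors (55.8% against 39.9%), and among the others the respiratory chain fell to 46.4% against 43.4%, while glycolysis (84.6% against 56.4%) and aminoacyl-tRNA synthetases (76.5% against 54.7%, 17 genes) kept larger differences than translation factors. Whether transcription itself draws signal cannot be told apart either. Of 23 sarcomere genes 17.4% were bound, with an exact 95% interval of 4.95 to 38.8. That share was below the 50.4% of genes matched on length and number of TSSs (adjusted permutation p = 0.00273), which goes against this explanation. It was also below the 40.5% of genes matched on head-to-head arrangement and number of TSSs, but without a call (adjusted permutation p = 0.0626). The interval includes the 34.0% of all genes, muscle is a part of the embryo, and no expression was measured. No biological explanation was tested for lack of a second group.

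The AT-rich summits are the last pattern. Where summits lie does not account for it, since their GC content was lower than that of windows of the same feature class on the same arm by a difference of -6.29 percentage points (95% interval -6.59 to -6.00). Promoter summits differed by -3.94 points (95% interval -4.34 to -3.54) from the same offset at TSSs with no peak. The 5000 lowest pooled peaks differed from windows of their class by -0.153 points (95% interval -0.536 to 0.206), but this does not exclude a GC bias of the libraries: peaks were ranked by signal, which such a bias would raise, mean GC rises along the pooled list from 34.7% to 41.4%, and the end of the list includes background. A GC bias, a preference of the protein for AT-rich sites and the low nucleosome occupancy of such DNA stay open, and no biological explanation was tested.

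The hypothesis that DRE promoters hold stronger peaks met the opposite result. Promoter peaks with a DRE had a median rank -11.8 percentile points from those without (231 and 3889 peaks, adjusted permutation p = 0.00168). In the replicates the difference was -11.0 ± 1.06 (SD, n = 3). Peaks with Ohler motif 1 were at -17.7 points and with Ohler motif 6 at -23.4, also past the threshold (adjusted permutation p of 0.00864 and 0.00298), and those with Ohler motif 7 at -0.133 (0.965).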
